A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

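Total RNA from 18 budding yeast cultures or culture aliquots was measured on Affymetrix expression arrays, 1 array per sample. Per the labels' protocols, cultures of 200 ml in synthetic medium lacking leucine were kept at 30 °C until the OD600 reached 0.4. Part of each was then treated with linoleic acid hydroperoxide (LoaOOH, 30 µM for 45 min), and biotin-labelled cRNA was made from 6 µg of total RNA. The labels give 3 genotypes, each with and without LoaOOH, and 3 replicates in each of the 6 groups. They do not say whether replicates were separate cultures, so a p-value here measures the spread between these samples, part of which may be technical. The sample descriptions carry the prefix CT for the 12 arrays of replicates 1 and 2 and the prefix JC for the 6 arrays of replicate 3. What the prefixes stand for is not given in the sources used here, and the JC arrays hold 1 sample per group.

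The deposited values were made by the authors with Affymetrix Expression Console and PLIER, per the submitters' processing notes, and they range from 2.47 to 15, as a log2 scale would. The log2 base was taken from that range. Versions, PLIER settings and any normalization between arrays are not given in the sources used here. All 18 columns were used and 0 were left out. No pair of arrays held identical values. Within groups, the SD across genes of the difference between 2 arrays ran from 0.168 to 0.35.

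The platform annotation was used to name probe sets. Of 10928 probe sets, 5498 are assigned to 1 Saccharomyces cerevisiae gene, 1746 to another organism on the same array, 1 to several genes and 166 are controls, and 3517 others are not named. Where a gene had several probe sets (47 genes), one without a suffix letter in its ID came first, then the one with the highest mean. This left 5449 genes, with no filter on dim ones. Chromosomes and systematic names come from the R64 assembly, and coordinates were used only to order the genes along chromosome V. The 95th percentile of the probe sets of another organism, 4.518 on the log2 scale, served as the background level. The means of 58 genes (1.06%) lay below it, and a fold against a group below background is given as a lower bound against that level.

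The plan was to normalize further only if array medians differed by more than 0.1 on the log2 scale, and it did not say over which probe sets. Over the tested genes the medians ran from 10.56 to 10.64, a range of 0.0771. Over all probe sets the range was 0.279. The decision was taken over the tested genes after both ranges were known, so the values were used as deposited, with quantile normalization as an alternative.

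Each comparison was a contrast in 1 limma model (R 4.3.3, limma 3.58.1) with 6 group means fitted to all 18 arrays, which share 1 estimate of the spread. Moderated statistics from eBayes were two-sided and adjusted by the Benjamini-Hochberg method over all 5449 genes at 0.05. The total degrees of freedom were 14.76, of which 12 are residual. The 10 comparisons are the LoaOOH response in each genotype, the difference of the response of each mutant from that of wild type, the 3 differences between genotypes in control cells and the differences of each mutant from wild type after LoaOOH. Values are given as log2 difference ± SE from this model with 3 arrays per group. The median SE was 0.102 for a response and 0.144 for a difference of responses. With 3 arrays per group, the number of arrays limits the precision.

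A total of 27 gene lists were fixed in advance: targets of the G1 transcription factors SBF and MBF, core histones, the G2/M CLB2 cluster, M/G1 genes, Yap1 antioxidant genes, Msn2/Msn4 general stress genes, Hsf1 chaperones, Pdr1/Pdr3 drug efflux genes, the proteasome, cytosolic ribosomal proteins, ribosome biogenesis, the pentose phosphate pathway, peroxisomal beta-oxidation, ergosterol and fatty acid synthesis, the iron regulon, sulfur amino acid synthesis, Gcn4 amino acid synthesis, the DNA damage response, cell wall integrity genes, oxidative phosphorylation, glycolysis, a-cell genes, alpha-cell genes, haploid-specific genes, meiosis and sporulation genes, and auxotrophic marker genes. Some genes belong to more than 1 list. The ribosomal protein list was drawn by a name pattern and also took in RPP1, a subunit of RNase P. Lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation beside it and with fry, each adjusted over the lists of a comparison. A list needed 5 measured genes, and the 4 alpha-cell genes were described and not tested. Adjusted p-values of lists are from camera with the preset correlation unless another test is named. With the estimated correlation and all 18 arrays, none of these lists passed 0.05 in any of the 10 comparisons. Without both C404A mutant replicate 2 arrays, 1 did, the drug efflux list in the wild type response (adjusted p = 0.0387). By fry with all 18 arrays, 5 lists passed in the wild type response, 5 in the deletant response and 0 in the C404A response. Without both C404A mutant replicate 2 arrays these were 7, 9 and 6. In either response difference 0 lists passed by fry with all 18 arrays.

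The text names 10 genes whatever their values (SWI6, SWI4, MBP1, CLN1, CLN2, CLN3, PCL1, HO, RNR1 and CDC21). It further names up to 10 genes with the largest rise and up to 10 with the largest fall, past the threshold and with groups that do not overlap, in the wild type response and the comparisons of each mutant with wild type in control cells, and up to 5 in the others. In the response differences the rule did not ask for groups that do not overlap. Up to 4 members with the smallest p serve as examples of a list. The mapping of samples, the design, the lists, this rule and most alternatives were chosen before the data were examined.

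Whether replicate numbers pair the samples was checked by the correlation, across genes, of the deviations of same-numbered arrays from their group means. All 3 correlations were above 0.1 between control and LoaOOH arrays of wild type (0.502 to 0.856) and of the C404A mutant (0.115 to 0.605). In the deletant they ran from 0.0548 to 0.264, and no combination of different genotypes passed. By that rule the numbers pair control with LoaOOH within wild type and within the C404A mutant. Failing the rule does not show that the deletant arrays were unpaired. The main model holds no term for pairing, so the response counts from it ignore the pairing. Blocked fits are given as alternatives. This check was made in the same run as the blocked fits, by a rule set in advance.

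Alternatives set in advance were quantile normalization, leaving out dim genes, adding an offset of 16 on the linear scale, the mean of probe sets, blocks for the replicate number and for the label prefix, the CT arrays alone, random blocks (duplicateCorrelation with statmod 1.5.0), the compared groups only, trended and robust variances, array weights, an unmoderated test, a minimum of 1.5-fold, and leaving out each array or replicate number. After the values were seen, fits were added without chromosome V genes, with the chromosome V shift removed, without both C404A mutant replicate 2 arrays, and with a fixed block per genotype and replicate number.

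The model was tested on simulated data drawn for the same 5449 genes with 200 of them changed. For the wild type response it recovered 71.6% of changes of 0.5 on the log2 scale, 95.5% of changes of 1 and 100% of changes of 2. For the difference between deletant and wild type responses it recovered 43.3%, 85.1% and 98.5%. Unchanged genes called were 13 in the first and 6 in the second. Noise was drawn independently for each gene and array, and the changes fell on randomly chosen genes. Real responses can lie in genes that vary more and vary together, so these shares need not hold for the responses seen here.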

Results

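Transcript levels were measured on 18 arrays of the budding yeast Saccharomyces cerevisiae. The cells were wild type, a deletant of SWI6, or a strain in which a cysteine of Swi6 was replaced by alanine (C404A). Swi6 is the shared subunit of SBF (Swi4 and Swi6) and MBF (Mbp1 and Swi6), the transcription factors that drive G1 gene expression. Each genotype was sampled without treatment and after 45 min in 30 µM LoaOOH, a lipid hydroperoxide that imposes oxidative stress, with 3 arrays in each of the 6 groups. The medians of the arrays over 5449 genes lay between 10.56 and 10.64 on the log2 scale. Genes named below for the size of a rise or fall had all 3 arrays of 1 group beyond all 3 of the other. Among markers of mating type, group means of STE2, the alpha-factor receptor of a cells, ran from 13.55 to 13.80 and of STE3, the a-factor receptor of alpha cells, from 7.85 to 8.09, while BAR1 ran from 12.48 to 12.83 and MFA1 from 12.45 to 13.05. MF(ALPHA)1, an alpha-factor gene, differed, at 5.59 in wild type, 7.285 in deletant and 6.314 in C404A control cells. Of the auxotrophic markers, URA3 (3.155 to 3.456) and MET17 (3.881 to 4.135) lay below the background of 4.518 in each group, and LEU2 lay at 14.22 to 14.39.

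SWI6 mRNA was near or below background in the arrays labelled deletant and abundant in the others. In control cells its mean log2 signal was 10.38 ± 0.21 in wild type, 10.23 ± 0.0763 in the C404A mutant and 3.446 ± 0.251 in the deletant (SD, n = 3). Wild type was at least 58.1-fold above the deletant (adjusted p = 2.49e-11), and the C404A mutant was at least 52.6-fold above it (adjusted p = 3.38e-11). After LoaOOH the levels were 10.54 ± 0.214 in wild type, 10.29 ± 0.169 in the C404A mutant and 3.7 ± 0.603 in the deletant (SD, n = 3), so wild type was at least 64.9-fold above the deletant (adjusted p = 3.04e-11). The C404A mutant differed from wild type by -0.14 in control cells (adjusted p = 0.725) and by -0.24 after LoaOOH (adjusted p = 0.559). A point mutation leaves the transcript in place, so SWI6 level checks the deletant labels and not those of the C404A mutant.

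Genes of chromosome V were higher in both mutants than in wild type, along the length of the chromosome. Over its 259 measured genes, the median difference in control cells was 0.758 (1.69-fold) for the deletant, with 256 genes (98.8%) higher, and 0.696 (1.62-fold) for the C404A mutant, with 253 genes (97.7%) higher. Limma called 213 of them higher and 1 lower in the deletant, and 212 higher and 0 lower in the C404A mutant. The median of chromosome V per array, set against the wild type control mean, was 0.748 ± 0.0585 in deletant control cells and 0.697 ± 0.0697 in C404A control cells (SD, n = 3). After LoaOOH it was 0.771 ± 0.0274 in the deletant and 0.696 ± 0.0527 in the C404A mutant (SD, n = 3). In 10 bins of the gene order it ran from 0.571 to 0.853 in the deletant and from 0.588 to 0.754 in the C404A mutant. The median differences over genes of all other chromosomes were -0.016 and -0.0402. SWI4 and RNR1 lie on chromosome V, and the gene totals of each genotype comparison below are therefore split into chromosome V and the other chromosomes. List results keep chromosome V members unless stated. Without chromosome V genes 10 lists passed instead of 6 for the deletant and 7 instead of 3 for the C404A mutant against wild type control. After LoaOOH these were 7 instead of 5 and 5 instead of 4. For the C404A mutant against the deletant 11 passed in both fits. With an estimated correlation 0 passed in each.

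**Figure D1:**
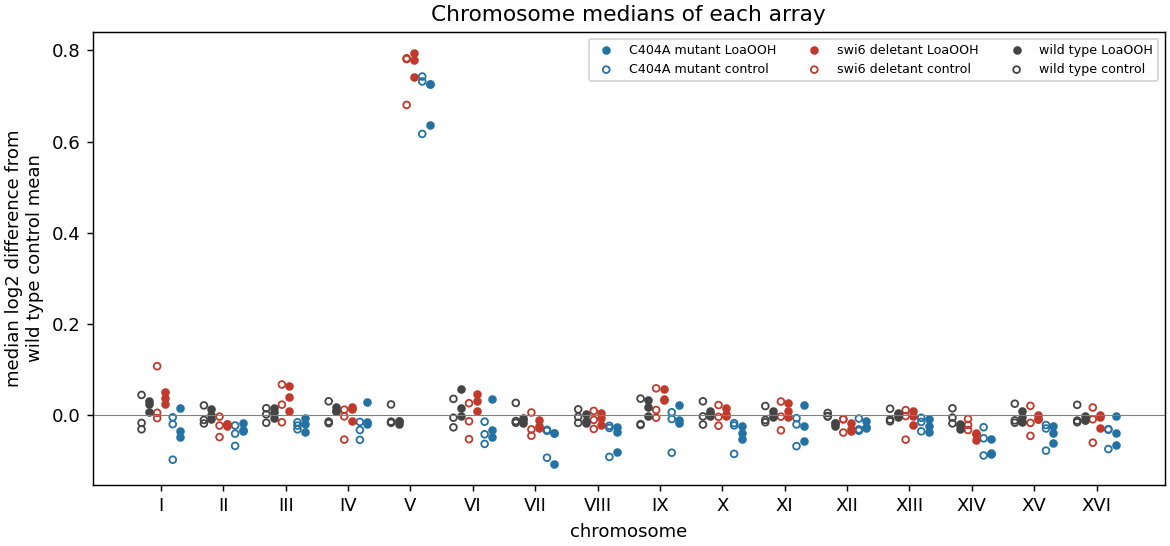
Median log2 difference of each of the 18 arrays from the wild type control mean, for each of the 16 chromosomes, with open points for control and filled points for LoaOOH arrays, and grey for wild type, red for the deletant and blue for the C404A mutant. On chromosome V the 12 arrays of the mutants lie between 0.6168 and 0.7945 and the 6 wild type arrays between -0.0188 and 0.02386, and medians of all other chromosomes lie between -0.107 and 0.1077.

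Apart from SWI6 itself, the gene that fell most in untreated deletant cells was TOS6, which encodes a cell wall protein. TOS6 fell by 5.97 ± 0.161 on the log2 scale (SE, 3 arrays per group), a 62.6-fold difference (adjusted p = 3.13e-12). CLB6, an S-phase cyclin, was 4.37-fold lower (adjusted p = 1.17e-07), HO, the endonuclease of mating-type switching, 4.11-fold lower (adjusted p = 1.15e-06) and SVS1, a cell wall protein, 4-fold lower (adjusted p = 1.09e-08). The phosphate transporter gene PHO84 fell by 3.55 ± 0.546 (adjusted p = 0.000314). In the other direction, the ammonium permease gene MEP2 rose 3.08-fold (adjusted p = 2.11e-06), the nuclease gene DIN7 2.82-fold (adjusted p = 8.27e-08) and the nitrogen catabolite repressor gene DAL80 2.33-fold (adjusted p = 7.11e-05).

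In total 551 genes differed between deletant and wild type control cells, 378 higher and 173 lower. Chromosome V held 213 of the higher genes (56.3%) and 1 of the lower, leaving 165 higher and 172 lower elsewhere. With the chromosome V shift removed from the mutant arrays the total was 324, with 153 higher and 171 lower, and without chromosome V genes in the fit it was 250. The other genes with the largest rises were MF(ALPHA)1 at 1.70 ± 0.212, which encodes alpha-factor, OPT2, an oligopeptide transporter gene, at 2.84-fold (SE 0.396 on the log2 scale), and on chromosome V CEM1, RTT105, PEA2, YER134C and FCY22 at 1.22 to 1.38. The other large falls were GRE1 at -2.34 (adjusted p = 0.0342), TIS11, a factor in mRNA decay under iron shortage, at -2.10 (adjusted p = 0.00401), INO1, inositol phosphate synthase, at -2.05 (adjusted p = 0.0185), and the cell wall gene HPF1 at -1.91 (adjusted p = 5.91e-06). SWI4 was higher by 1.12 (adjusted p = 0.000184) and differed by 0.36 with the chromosome V shift removed (adjusted p = 0.182). The G1 cyclin gene CLN2 was lower by -0.33 ± 0.101 (adjusted p = 0.0488). CLN1 differed by -0.14 (adjusted p = 0.404), PCL1 by -0.26 (adjusted p = 0.264), CLN3 by 0.07 (adjusted p = 0.765), MBP1 by -0.11 (adjusted p = 0.583), RNR1 by 0.21 (adjusted p = 0.271) and CDC21 by 0.24 (adjusted p = 0.125).

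Of 28 SBF targets, 10 fell and 4 rose in the deletant, over all genes as well as adjusted over the list alone (list adjusted p = 0.00517, median -0.10, mean -0.45). Besides TOS6, SVS1 and HO, the exoglucanase gene EXG1 fell by 0.40 (adjusted p = 1.63e-05). The MBF targets moved both ways. Of 35, 8 rose and 4 fell, and 13 rose and 5 fell adjusted over the list alone (list adjusted p = 0.0752, median 0.15). Without chromosome V genes 6 of 33 rose and 4 fell (list adjusted p = 0.0155, adjusted p = 0.898 with an estimated correlation). PLM2, a chromatin-associated factor induced by DNA damage, rose by 1.20 ± 0.0962 (adjusted p = 6.14e-07) and the cohesin gene IRR1 by 0.45. CLB6, given above, is among the MBF targets that fell. Of 17 cell wall integrity genes, 5 fell (6 adjusted over the list alone, list adjusted p = 0.00286), among them CWP1 at -1.10, and of the iron regulon 5 fell and 1 rose (9 and 1 adjusted over the list alone, list adjusted p = 0.0144), among them the ferric reductase gene FRE1 at -1.10 (adjusted p = 9.07e-06). These lists had adjusted p = 0.768 with an estimated correlation. The Msn2/Msn4 list was lower (median -0.16, 3 fell and 1 rose, list adjusted p = 0.032), as were ribosomal proteins (median -0.04, list adjusted p = 0.0186) and ribosome biogenesis (median -0.13, list adjusted p = 0.0186), each with adjusted p = 0.826 with an estimated correlation. The DNA damage response list held 4 genes that rose and 2 that fell (list adjusted p = 0.0571), among them RAD54, a recombination gene, at 0.79 ± 0.0591 and DUN1, a checkpoint kinase gene, at 0.82. DUN1 and PLM2 are on the MBF list as well, so these lists overlap. Without chromosome V genes the DNA damage list passed (0.0109, adjusted p = 0.534 with an estimated correlation). So did the G2/M cluster (0.0213, 0.898) and Hsf1 chaperones (0.0312, 0.875). In that fit 8 SBF targets fell and 2 rose, 3 cell wall integrity genes fell, and 3 iron genes fell and 1 rose. CLN2 lost its call without each single array of either group (adjusted p from 0.0806 to 0.161) and without chromosome V genes (0.0761). OPT2 lost its call without wild type control replicate 1 (0.126), deletant control replicate 2 (0.0676) or replicate 3 (0.0866), INO1 without wild type control replicate 1 (0.104) or replicate 2 (0.074) or deletant control replicate 1 or 3 (0.0548 each), and GRE1 without any single array except wild type control replicate 3 (0.0794 to 0.18 for the others).

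Untreated C404A cells had lower levels of PHO84, ZRT1, ARG3 and HXT1 than wild type and higher levels of most chromosome V genes. HO differed from wild type by -0.07 (adjusted p = 0.837), CLN1 by 0.25 (adjusted p = 0.107) and CLN2 by 0.11 (adjusted p = 0.524). PHO84 fell by 2.97 ± 0.546 (SE, 3 arrays per group), which is 7.84-fold (adjusted p = 0.00216). The zinc transporter gene ZRT1 was 2.77-fold lower, the arginine synthesis gene ARG3 2.29-fold lower and the glucose transporter gene HXT1 2.06-fold lower (adjusted p = 1.85e-05). CSM3, a replication fork protein gene on chromosome XIII, rose by 1.19 ± 0.0814 or 2.28-fold (adjusted p = 3.28e-07), where the deletant differed from wild type by 0.07 (adjusted p = 0.705).

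In total 449 genes differed between C404A and wild type control cells, 306 higher and 143 lower, and chromosome V held 212 of the higher (69.3%) and 0 of the lower, leaving 94 higher and 143 lower elsewhere. With the chromosome V shift removed the total was 180, with 59 higher and 121 lower, and without chromosome V genes in the fit it was 94. Apart from CSM3, the largest rises were all on chromosome V, with FAA2, an acyl-CoA synthetase gene, at 1.37 ± 0.196 and YER078W-A, YER137C, TIR1, RGI1, CEM1, YAT2, ADK2 and YER034W at 1.15 to 1.36. The other large falls were PHO5 at -1.40 (adjusted p = 0.0218), HPF1 at -1.26 (adjusted p = 0.000472), TIR3 at -0.93, AAH1 at -0.84, GDH3 at -0.84 and KDX1 at -0.82. SWI4 (0.97, adjusted p = 0.000964) and RNR1 (0.53, adjusted p = 0.00412), both on chromosome V, were higher. With the chromosome V shift removed they differed by 0.23 (adjusted p = 0.368) and -0.21 (adjusted p = 0.273). CLN3 differed by -0.31 (adjusted p = 0.0953), PCL1 by 0.24 (adjusted p = 0.26), MBP1 by -0.17 (adjusted p = 0.331) and CDC21 by -0.15 (adjusted p = 0.312).

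The ribosome biogenesis list was lower in the C404A mutant (median -0.27, list adjusted p = 7.21e-05). Of 42, 3 fell and 2 rose, and 15 fell and 2 rose adjusted over the list alone, with ERB1 up by 0.66 (adjusted p = 0.0034) and RRP9 down at -0.38. Of the 17 cell wall integrity genes 3 fell (8 adjusted over the list alone, median -0.25, list adjusted p = 0.00177). Of the 35 MBF targets 3 fell and 2 rose, the latter SWI4 and RNR1 on chromosome V (4 and 2 adjusted over the list alone, median -0.13, list adjusted p = 0.0437). Among those that fell was POL1, DNA polymerase alpha, at -0.41 (adjusted p = 0.00034). These 3 lists had adjusted p = 0.876 with an estimated correlation. Without chromosome V genes 3 of 33 MBF targets fell and 0 rose (list adjusted p = 0.00314). Of 41 ribosome biogenesis genes 0 fell and 1 rose (7.42e-06), and 1 cell wall integrity gene fell (0.000926). Hsf1 chaperones and oxidative phosphorylation (0.0132 each), the iron regulon (0.0381) and M/G1 genes (0.0462) passed in that fit as well. Each had adjusted p = 0.86 there with an estimated correlation. Of the 28 SBF targets MNN1 rose (0.88, on chromosome V) and TOS8 fell (-0.50), with list adjusted p = 0.281. The total was 264 in the CT arrays alone, 268 without wild type control replicate 1, 297 without wild type control replicate 3 and 274 without C404A control replicate 3. PHO5 lost its call without each of these arrays (adjusted p = 0.11, 0.0845 and 0.0939), and GDH3 lost its call without any single array except wild type control replicate 3 (0.0515 to 0.149 for the others).

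Set directly against the deletant, the C404A mutant had higher levels of several SBF targets and lower levels of several MBF and DNA damage genes in untreated cells. The SBF targets TOS6 (54.9-fold, 5.78 ± 0.161, adjusted p = 5.01e-12), SVS1 (4.08-fold) and HO (3.91-fold, adjusted p = 7.67e-06) were higher. CLB6, which is on the MBF list, was higher too, 4.22-fold (adjusted p = 2.95e-07), against the direction of most MBF targets. DIN7 was 2.93-fold lower (-1.55 ± 0.0949, adjusted p = 1e-07) and PLM2 2.42-fold lower (adjusted p = 9.7e-07), followed by MEP2 at -1.08 (adjusted p = 0.000825), the urea transporter gene DUR3 at -1.02 (adjusted p = 0.00939) and MF(ALPHA)1 at -0.97 (adjusted p = 0.0298). In total 98 genes differed, 39 higher and 59 lower, with 2 of each on chromosome V.

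Of the 28 SBF targets 11 were higher and 0 lower (13 and 3 adjusted over the list alone), with list adjusted p = 9.16e-09, median 0.12 and mean 0.51 (adjusted p = 0.221 with an estimated correlation). CLN1 was higher by 0.39 (adjusted p = 0.041) and CLN2 by 0.44 (adjusted p = 0.0357). PCL1 differed by 0.50 (adjusted p = 0.0708), CLN3 by -0.39 (adjusted p = 0.104), SWI4 by -0.15, MBP1 by -0.06 and RNR1 by 0.32 (adjusted p = 0.169). Of the 35 MBF targets 10 were lower and 1 higher (17 and 3 adjusted over the list alone, median -0.25, list adjusted p = 8.56e-08, adjusted p = 0.497 with an estimated correlation), among them the thymidylate synthase gene CDC21 at -0.39 (adjusted p = 0.04). The DNA damage list had 4 lower genes, RAD54 (-0.78) and DUN1 (-0.76) among them (list adjusted p = 0.00135, adjusted p = 0.12 with an estimated correlation). DUN1 and PLM2 are on the MBF list as well. Oxidative phosphorylation was higher (median 0.17, list adjusted p = 8.93e-07) and M/G1 genes lower (median -0.15, list adjusted p = 0.000658), both with adjusted p = 0.497 with an estimated correlation, and Msn2/Msn4 genes were higher (median 0.13, list adjusted p = 0.000213, adjusted p = 0.727 with an estimated correlation). Smaller shifts that passed were higher levels of beta-oxidation (median 0.15, list adjusted p = 0.0153, adjusted p = 0.727 with an estimated correlation), histones (0.11, 0.0305) and drug efflux genes (0.16, 0.0305), both with adjusted p = 0.719 with an estimated correlation, and lower levels of a-cell genes (-0.26, 0.03, adjusted p = 0.727 with an estimated correlation) and ribosome biogenesis (-0.13, 0.0305, adjusted p = 0.851 with an estimated correlation). None of these 5 passed without both C404A replicate 2 arrays (list adjusted p from 0.13 to 0.558). CLN1 and CLN2 lost their calls without any single array of these groups except C404A control replicate 1 (adjusted p from 0.0728 to 0.174 and from 0.0942 to 0.147), and CDC21 without any except C404A control replicate 2 (0.0855 to 0.222). MF(ALPHA)1 lost its call without any except C404A control replicate 1 (0.0552 to 0.124), and the total was 40 without deletant control replicate 3, 56 without deletant control replicate 2, 50 without C404A control replicate 3, 65 without C404A control replicate 2 and 15 in the CT arrays alone.

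**Figure D2:**
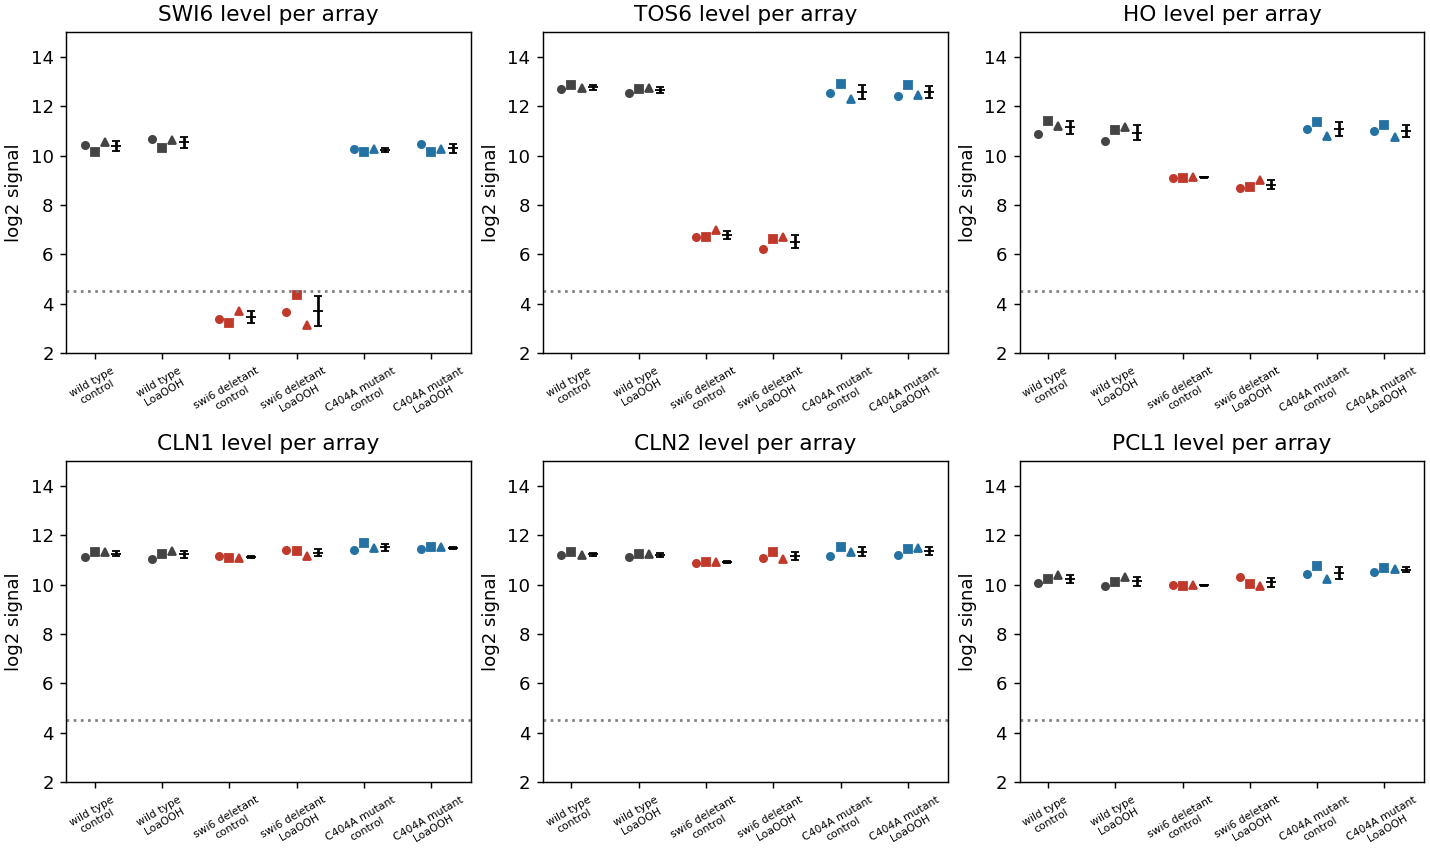
Log2 signal of SWI6, TOS6, HO, CLN1, CLN2 and PCL1 on each array by group, with circles, squares and triangles for replicates 1, 2 and 3, black bars for the mean ± SD (n = 3) and a dotted line at the background of 4.518. SWI6 lies at 3.446 in deletant control cells, TOS6 is 62.6-fold lower there than in wild type, and CLN1 differs between these groups by -0.14.

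Wild type cells answered LoaOOH with higher expression of several peroxisomal fatty acid breakdown genes. POT1, the peroxisomal thiolase, rose by 3.16 ± 0.541 (SE, 3 arrays per group) or 8.93-fold (adjusted p = 0.0426). The acyl-CoA oxidase gene POX1 rose 4.34-fold, the uncharacterised gene YHR140W 4.07-fold, PEX18, which helps import thiolase into peroxisomes, 3.04-fold (adjusted p = 0.0449), the enoyl-CoA isomerase gene ECI1 2.37-fold, FAA2 2.19-fold and IDP3, peroxisomal isocitrate dehydrogenase, 1.82-fold. DBP2, an RNA helicase gene, fell by 0.91 ± 0.176 (adjusted p = 0.048) and RPF2, a ribosome assembly factor, by 0.57 ± 0.105. None of these genes kept its call with a fixed block per genotype and replicate number. A random block within genotype, which also takes up the pairing, called more genes than the main fit, as given under the dependence on processing. The intervals of the G1 cyclin genes included 0, with CLN1 at -0.04 (95% interval -0.238 to 0.155, adjusted p = 0.875), CLN2 at -0.02 (-0.235 to 0.196, adjusted p = 0.956) and PCL1 at -0.09 (-0.37 to 0.183, adjusted p = 0.784).

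In total 14 genes were called in wild type, 9 higher and 5 lower. The remaining ones were YGR174W-A and YLR152C (0.55), which rose, and YPL245W (-0.44), the zinc homeostasis gene IZH3 (-0.39) and RPO31, the largest subunit of RNA polymerase III (-0.33), which fell. YGR174W-A had a mean of 4.475 in control cells, below background, and of 5.207 after LoaOOH. Of the genes fixed in advance, SWI4 differed by 0.21 (adjusted p = 0.558), MBP1 by 0.14 (adjusted p = 0.528), CLN3 by -0.03 (adjusted p = 0.927), HO by -0.23 (adjusted p = 0.555), RNR1 by -0.09 (adjusted p = 0.715) and CDC21 by 0.08 (adjusted p = 0.7). At an unadjusted p under 0.05 there were 1027 genes.

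The Msn2/Msn4 general stress list rose as a group (median 0.49 over 32 genes, list adjusted p = 2.66e-18), with 0 members called over all genes and 27 that rose adjusted over the list alone. Its smallest p-values were those of the phosphoglucomutase gene PGM2 (0.84, adjusted p = 0.0585), SOL4 (1.08, adjusted p = 0.0585) and the catalase gene CTT1 (1.17, adjusted p = 0.0589). Ribosome biogenesis fell (median -0.39 over 42 genes, list adjusted p = 6.72e-22), with 0 called over all genes and 39 that fell adjusted over the list alone, and RPA135, a subunit of RNA polymerase I, at -0.52 (adjusted p = 0.0585). Beta-oxidation rose (median 0.41 over 19 genes, list adjusted p = 3.69e-11), with 5 genes over all and 10 adjusted over the list alone. These 3 lists had adjusted p = 0.207 with an estimated correlation. Pdr1/Pdr3 drug efflux genes rose (median 0.41 over 16 genes, list adjusted p = 1.28e-07, adjusted p = 0.182 with an estimated correlation, and 0.0387 without both C404A replicate 2 arrays), with 0 over all genes and 10 adjusted over the list alone. Among them PDR5, a multidrug transporter gene, was at 0.81, YOR1 at 0.86 and PDR15 at 1.54 (adjusted p = 0.0585 each). Yap1 antioxidant genes rose (median 0.16 over 25 genes, list adjusted p = 5.53e-05, adjusted p = 0.503 with an estimated correlation), with 0 over all genes and 4 adjusted over the list alone. OYE3, an NADPH oxidoreductase gene, was at 2.12 (adjusted p = 0.09), the peroxiredoxin gene PRX1 at 0.76 (adjusted p = 0.102) and the thioredoxin gene TRX2 at 0.37 (adjusted p = 0.0634).

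A further 8 lists passed with smaller medians. Rises were in the proteasome (median 0.0858, list adjusted p = 7.03e-05, adjusted p = 0.393 with an estimated correlation), oxidative phosphorylation (0.11, 0.00171, adjusted p = 0.608 with an estimated correlation), Hsf1 chaperones (0.063, 0.00705, adjusted p = 0.575 with an estimated correlation) and cell wall integrity (0.162, 0.0355, adjusted p = 0.664 with an estimated correlation). Falls were in ribosomal proteins (-0.0395, 0.00224) and Gcn4 targets (-0.0833, 0.00495), both with adjusted p = 0.664 with an estimated correlation, and in ergosterol and fatty acid synthesis (-0.0439, 0.042) and the iron regulon (-0.0768, 0.042), both with adjusted p = 0.608 with an estimated correlation. Adjusted over the list alone, 3 iron genes fell, with the permease gene FTR1 at -1.14 (adjusted p = 0.0587 over all genes) and FET4 at -0.85 (0.0585). The SBF list (median -0.066, list adjusted p = 0.0887) and the MBF list (-0.0714, 0.226) did not pass, with GIC1 at -0.29 (adjusted p = 0.111) and POL1 at -0.16 (adjusted p = 0.154) as examples. Lists that did not pass either were the G2/M cluster (-0.0587, 0.053), histones (-0.0653, 0.226), M/G1 genes (-0.0447, 0.708), the pentose phosphate pathway (0.0408, 0.114), sulfur amino acids (0.0452, 0.583), the DNA damage response (median -0.00123, mean 0.0139, 0.853), glycolysis (0.0245, 0.173), a-cell genes (0.0402, 0.505), haploid-specific genes (0.0116, 0.415), meiosis genes (0.0431, 0.452) and auxotrophic markers (0.0358, 0.505), each with its median and list adjusted p. The gene total was 1 with a fixed block per genotype and replicate number (YGR174W-A, with the other 13 at an adjusted p of 0.0667 or 0.0671), and ergosterol synthesis had list adjusted p = 0.0593 there. The iron regulon had list adjusted p = 0.128 without chromosome V genes. It was 0 with the label prefix as a block, 0 in the CT arrays alone, 0 or 1 without any single array of these groups, and 479 (179 higher, 300 lower) without both C404A replicate 2 arrays, which enter through the shared estimate of the spread.

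In the swi6 deletant LoaOOH raised 8 of 19 beta-oxidation genes, TSA2 and OYE3 and lowered 4 of 21 iron regulon genes. POT1 rose by 2.91 or 7.52-fold, POX1 4.66-fold (adjusted p = 0.0281), the peroxiredoxin gene TSA2 by 2.73 ± 0.43 or 6.65-fold (SE, 3 arrays per group, adjusted p = 0.0249) and OYE3 6.98-fold (adjusted p = 0.0381). INO1 (2.52) and YHR140W (2.43) rose too. FTR1 fell by 1.31 ± 0.258 (adjusted p = 0.0281) and the ferroxidase gene FET3 by 1.14 (adjusted p = 0.0343), followed by YKR075C (-1.10), YLR108C (-0.97) and the adenine deaminase gene AAH1 (-0.90). CLN2 differed by 0.26 (adjusted p = 0.157), and SRL1, an SBF target, fell by 0.38 (adjusted p = 0.0343).

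Across 5449 genes the LoaOOH responses of the deletant and wild type correlated at 0.899. At an unadjusted p under 0.05 there were 1161 genes in the deletant and 1027 in wild type. After adjustment 194 genes changed in the deletant, 99 higher and 95 lower. Msn2/Msn4 genes rose (median 0.61, list adjusted p = 3.11e-19), 14 of 32 over all genes and 27 adjusted over the list alone, among them the heat shock gene HSP12 at 0.90 ± 0.141 (adjusted p = 0.0249) and MSC1 at 1.15. Ribosome biogenesis fell (median -0.39, list adjusted p = 3.47e-20), 7 of 42 over all genes and 39 adjusted over the list alone, among them NOP2 at -0.45 (adjusted p = 0.0285). Beta-oxidation rose (median 0.46, list adjusted p = 3.5e-09), 8 of 19 over all genes and 11 adjusted over the list alone, with SPS19 at 1.33. Drug efflux genes rose (median 0.44, list adjusted p = 1.35e-06), 5 of 16 over all genes and 10 adjusted over the list alone, with YOR1 at 0.90 and PDR5 at 0.77. These 4 lists had adjusted p = 0.247 with an estimated correlation. Yap1 genes rose (median 0.12, list adjusted p = 0.000956, adjusted p = 0.661 with an estimated correlation), 2 over all genes and 5 adjusted over the list alone, and of the iron regulon 4 genes fell in both counts (median -0.09, list adjusted p = 0.0111, adjusted p = 0.66 with an estimated correlation). Smaller shifts that passed were ribosomal proteins (median -0.06, list adjusted p = 4.38e-07), Gcn4 targets (-0.13, 0.000693), oxidative phosphorylation (0.11, 0.002), histones (-0.11, 0.0447) and cell wall integrity (0.14, 0.0492), each with adjusted p = 0.661 with an estimated correlation. The SBF list (median 0.04, list adjusted p = 0.857) and the MBF list (-0.04, 0.259) did not pass. Without chromosome V genes histones (0.0516), the iron regulon (0.0555) and cell wall integrity (0.055) did not pass, nor did histones with quantile normalization (0.0677). The total was 0 without deletant LoaOOH replicate 1 or 2 or deletant control replicate 2 or 3, 59 without LoaOOH replicate 3 and 14 without control replicate 1. It was 0 with the label prefix as a block and 0 in the CT arrays alone, and 535 (220 higher, 315 lower) without both C404A replicate 2 arrays.

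In the C404A mutant Msn2/Msn4, beta-oxidation, Yap1 and drug efflux genes rose after LoaOOH and ribosome biogenesis genes fell. This held for lists by camera with the preset correlation, with no single gene past the threshold. By fry these lists did not pass (adjusted p from 0.29 to 0.319). POT1 differed by 1.81 ± 0.541 or 3.52-fold (SE, 3 arrays per group), OYE3 by 2.11 or 4.32-fold, ECI1 by 0.85, FAA2 by 0.72 and IDP3 by 0.55, each with adjusted p = 0.793. Limma called 0 genes, 319 genes had an unadjusted p under 0.05, and the unmoderated test, trended and robust variances and array weights all called 0. Msn2/Msn4 genes rose as a list (median 0.28, list adjusted p = 2.11e-12, 0 called adjusted over the list alone), ribosome biogenesis fell (-0.22, 1.57e-16, 0 adjusted over the list alone), and beta-oxidation (0.24, 4.92e-09, 7 adjusted over the list alone), Yap1 genes (0.18, 3.58e-08) and drug efflux genes (0.24, 2.38e-05, 3 adjusted over the list alone) rose, each with adjusted p = 0.343 with an estimated correlation. Ribosomal proteins (-0.04, 2.38e-05), oxidative phosphorylation (0.07, 0.0015), cell wall integrity (0.15, 0.00574), ergosterol synthesis (-0.04, 0.0341), the iron regulon (-0.05, 0.0416) and the proteasome (0.03, 0.049) passed as well with adjusted p = 0.703 with an estimated correlation, as did Gcn4 targets (-0.07, 0.00574, adjusted p = 0.718 with an estimated correlation). The SBF list (median -0.01, list adjusted p = 0.472) and the MBF list (-0.05, 0.137) did not pass. With a fixed block per genotype and replicate number the proteasome (0.0697) and ergosterol synthesis (0.0683) did not pass. The proteasome did not pass with quantile normalization (0.244) or without chromosome V genes (0.0741) either, nor the iron regulon without chromosome V genes (0.133).

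The replicates of the C404A mutant differed in direction. Between same-numbered arrays, the median change of the Msn2/Msn4 list was 0.508 in replicate 1, -0.206 in replicate 2 and 0.441 in replicate 3, and that of ribosome biogenesis was -0.401, 0.115 and -0.431. Across genes, the LoaOOH minus control difference of C404A replicate 2 correlated with those of the other 8 pairs at -0.603 to -0.214, where the other 8 correlated among themselves at 0.458 to 0.848. Without both C404A replicate 2 arrays, 217 genes changed in the C404A mutant, 92 higher and 125 lower. POT1 then rose by 2.98 ± 0.36 (SE, 2 arrays per group) or 7.91-fold (adjusted p = 0.00164), OYE3 10.3-fold (adjusted p = 0.00567) and TSA2 4.94-fold, while FTR1 fell by 1.08 (adjusted p = 0.0168) and DBP2 by 0.94 ± 0.124 (adjusted p = 0.00219). In that fit 11 Msn2/Msn4 genes rose over all genes and 24 adjusted over the list alone (median 0.51, list adjusted p = 3.66e-17, adjusted p = 0.124 with an estimated correlation), and 11 ribosome biogenesis genes fell over all genes and 35 adjusted over the list alone (-0.41, 3.26e-22, adjusted p = 0.0995 with an estimated correlation). CLN1 differed by 0.04 (adjusted p = 0.898) and CLN2 by 0.09 (adjusted p = 0.743) there. The total was 183 without LoaOOH replicate 2 alone and 14 without control replicate 2 alone.

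**Figure D3:**
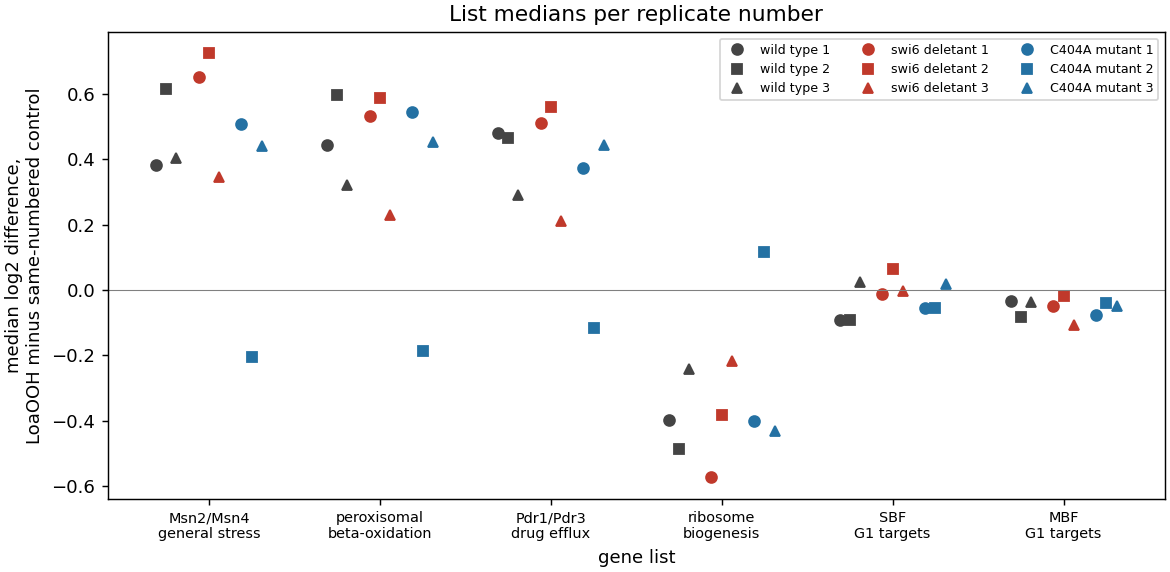
Median log2 difference between LoaOOH and same-numbered control arrays for the Msn2/Msn4, beta-oxidation, drug efflux, ribosome biogenesis, SBF and MBF lists, by genotype and replicate number. For Msn2/Msn4 genes the wild type pairs lie at 0.384, 0.615 and 0.406 and the C404A pairs at 0.508, -0.206 and 0.441.

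Whether Swi6 shapes the response was asked by testing the difference between responses. CLN1 and CLN2 had responses 0.23 ± 0.13 (95% interval -0.0487 to 0.507) and 0.28 ± 0.143 (-0.0294 to 0.581) higher in the deletant than in wild type, with intervals that include 0 (SE, 3 arrays per group). The differences were 0.02 (-0.254 to 0.301) and 0.05 (-0.251 to 0.359) for the C404A mutant. For PCL1 they were 0.22 (-0.175 to 0.608) and 0.23 (-0.164 to 0.619), and for POT1 the C404A mutant differed by -1.35 ± 0.765. The POT1 value rests in part on the C404A replicate 2 arrays, since without both the rises given above for the mutant and wild type lay close together. Every gene had an adjusted p of 1. Limma called 0 genes in either difference, with 20 genes for the deletant and 33 for the C404A mutant at an unadjusted p under 0.05, and the unmoderated test called 0 in both. As a list, SBF targets responded higher in the deletant than in wild type (median difference 0.07, list adjusted p = 0.00221, adjusted p = 0.691 with an estimated correlation), with HCM1 at 0.34 and GIC1 at 0.25, and it did not pass without replicate 1 (0.0857) or replicate 2 (0.349). In the C404A mutant the Msn2/Msn4 list responded less than in wild type (median difference -0.23, list adjusted p = 3.44e-10) and ribosome biogenesis fell less (0.16, 3.44e-10), each with adjusted p = 0.424 with an estimated correlation. Without both C404A replicate 2 arrays these lists had adjusted p = 0.961 and 0.555 and medians of the opposite sign.

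After LoaOOH the deletant had lower levels than wild type of TOS6, PHO84, SVS1 and HO, as it had without treatment. TOS6 was 70.5-fold lower (-6.14 ± 0.161, SE, 3 arrays per group, adjusted p = 2.07e-12), PHO84 14.3-fold (adjusted p = 0.000144), SVS1 4.73-fold and HO 4.32-fold (adjusted p = 7.33e-07). DIN7 was 3.07-fold higher (adjusted p = 3.11e-08), followed by MEP2 at 1.49, OPT2 at 1.44, PLM2 at 1.39 and, on chromosome V, AVT2 at 1.37. CLN1 differed by 0.09 (adjusted p = 0.65), CLN2 by -0.06 (adjusted p = 0.812), PCL1 by -0.04 (adjusted p = 0.902) and RNR1 by 0.30 (adjusted p = 0.0936), and SWI4 was higher by 1.22. In total 567 genes differed, 401 higher and 166 lower, with 215 of the higher (53.6%) and 0 of the lower on chromosome V. With the chromosome V shift removed they were 325, with 156 higher and 169 lower, and without chromosome V genes in the fit 255. Of the iron regulon 9 genes were lower and 1 higher in both counts, over all genes and adjusted over the list alone (median -0.25, list adjusted p = 0.00191, adjusted p = 0.521 with an estimated correlation), with FET3 at -1.23 and the heme oxygenase gene HMX1 at -1.38. Cell wall integrity (median -0.22, list adjusted p = 0.00166), ribosomal proteins (-0.07, 4.4e-05) and ribosome biogenesis (-0.15, 0.0145) were lower with adjusted p = 0.93 with an estimated correlation, and the DNA damage response was higher (0.06, 0.0228, adjusted p = 0.464 with an estimated correlation). Of the SBF targets 8 were lower and 5 higher (8 and 9 adjusted over the list alone, median -0.02, mean -0.39, list adjusted p = 0.164), and of the MBF targets 10 were higher and 2 lower (13 and 6 adjusted over the list alone, list adjusted p = 0.156). OPT2 lost its call without any single array except wild type LoaOOH replicate 3 (adjusted p from 0.0505 to 0.158).

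After LoaOOH the C404A mutant had lower levels than wild type of the phosphate transporter gene PHO84 and of PHO5 and PHO11, acid phosphatase genes, and higher levels of most chromosome V genes. PHO84 was 8.64-fold lower (adjusted p = 0.00146), YHR022C 3.27-fold (-1.71 ± 0.303, SE, 3 arrays per group, adjusted p = 0.00162), and PHO5 (-1.33, adjusted p = 0.0292), HPF1 (-1.32) and PHO11 (-1.18, adjusted p = 0.0184) were lower. TIR1 was 2.62-fold higher, with YER137C, ADK2, YER034W and CIN8 at 1.15 to 1.26, all on chromosome V. PCL1 was higher by 0.47 (adjusted p = 0.0384), CLN1 differed by 0.28 (adjusted p = 0.0861), CLN2 by 0.16 (adjusted p = 0.356) and HO by 0.07 (adjusted p = 0.859), and TOS8 was lower at -0.71 (adjusted p = 0.0022). In total 402 genes differed, 291 higher and 111 lower, with 209 of the higher (71.8%) and 0 of the lower on chromosome V. With the chromosome V shift removed they were 157, with 59 higher and 98 lower, and without chromosome V genes in the fit 69. Of the SBF targets 3 were higher and 1 lower (5 and 1 adjusted over the list alone, median 0.12, list adjusted p = 0.0398), and of the MBF targets 3 were lower and 2 higher (6 and 2 adjusted over the list alone, -0.14, 0.0398). Cell wall integrity (-0.25, 0.0012) and Msn2/Msn4 genes (-0.26, 0.0258) were lower, and these 4 lists had adjusted p = 0.9 with an estimated correlation. Without both C404A replicate 2 arrays the SBF list (0.196), the cell wall integrity list (0.0503) and the Msn2/Msn4 list (0.765) did not pass. PCL1 kept its call without wild type LoaOOH replicate 3 or C404A LoaOOH replicate 1 and lost it without any other single array (adjusted p from 0.0956 to 0.161), and PHO5 lost its call without wild type LoaOOH replicate 1 (0.13) or 3 (0.122) or C404A LoaOOH replicate 2 (0.063) or 3 (0.106).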

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

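In this part the tests of normalization and of Swi6 activity for chromosome V, of exchanged labels, an untreated sample and genotype for the C404A replicate 2 arrays, and of the replicate numbers for the SBF list were chosen after the results they measure were seen.

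Every array of both mutants carried higher levels of chromosome V genes than every wild type array. An error of normalization or hybridisation is argued against by the other chromosomes, whose largest absolute median in the mutant arrays was 0.108. Loss of Swi6 activity in the sampled cells as the cause is argued against by the C404A mutant. That mutant keeps the SBF-dependent genes TOS6 and HO far above the deletant yet shares the shift. Its C404A minus deletant median was -0.0515 of the deletant minus wild type median. A shift kept from an earlier loss of Swi6 activity is not excluded, since this test reads only the sampled cells. A response of some genes or 1 region is argued against by the lowest bin, at 0.571 in the deletant. For an extra copy of the whole chromosome in both strains, the 10 bins in each strain lay within the range set for it, between 0.571 and 0.853. That range was wide, and every bin fell short of a full doubling. An extra chromosome V may account for the shift, as a hypothesis that DNA content would test.

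The C404A replicate 2 pair moved against the other 8 pairs, with a pair score of -0.246 where the others ran from 0.711 to 1.1. The score weights all tested genes by a LoaOOH response. That was the response of wild type for the deletant, of the deletant for wild type, and the mean of both for the C404A mutant. A response weaker in every pair of the C404A genotype is argued against by its other pairs, with a mean score of 0.949. A response that varies more between samples of this genotype stays open, because these pairs were left after the opposite one was set aside. Array quality stays open. The background of its arrays was 3.665 at the farther one, where the other 16 arrays ran from 3.629 to 3.69. A value within that range excludes nothing here, because the pair also holds the array with the largest residual spread. Its LoaOOH array had the largest residual SD (0.203) and the lowest array weight (0.395), to which an opposite response adds by itself. Its control array had a score of -0.0482, between the other control arrays (-0.625 to -0.304) and the other LoaOOH arrays (0.256 to 0.695), and its LoaOOH array had -0.294, just above the other control arrays. Scores were set against the mean of all arrays of a genotype, so this pair itself moves the C404A scores. The small gap between its LoaOOH array and the other control arrays therefore decides nothing. Exchanged labels of the pair and an untreated sample on its LoaOOH array cannot be told apart, because the control array lies in neither range and this is a single pair. The values without the pair stand beside the values with it, and the labels were kept as given.

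The test of the difference between responses singled out the SBF list in the deletant against wild type (list adjusted p = 0.00221, median 0.07, adjusted p = 0.691 with an estimated correlation). Whether members already low in untreated deletant cells account for it stays open. The 14 members not called there gave a camera p of 2.43e-05, against 0.00034 for all 28, but this decides nothing, since leaving out the called members removed 4 that rose along with the 10 that fell and rests on the control arrays that also enter the difference. The list rests in part on replicates 1 and 2. The unadjusted camera p was 0.161 without replicate 2, 0.0312 without replicate 1 and 3.63e-06 without replicate 3, with the same direction each time. Adjusted over the lists, it did not pass without replicate 1 either. A difference between genotypes stays open, as a hypothesis that this test of single replicate numbers does not settle.

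The same test singled out other lists, given as values. In the deletant against wild type these were Hsf1 chaperones (list adjusted p = 3.25e-05, median -0.05, adjusted p = 0.524 with an estimated correlation), the proteasome (2.94e-12, -0.08, adjusted p = 0.149 with an estimated correlation) and ribosomal proteins (0.000137, -0.03, adjusted p = 0.997 with an estimated correlation). In the C404A mutant against wild type they were Msn2/Msn4 genes (3.44e-10, -0.23), Hsf1 chaperones (0.00218, -0.07), drug efflux genes (0.000164, -0.17), the proteasome (0.000341, -0.05), beta-oxidation (5.39e-06, -0.20) and ribosome biogenesis (3.44e-10, 0.16), each with adjusted p = 0.424 with an estimated correlation. Without both C404A replicate 2 arrays none of these 6 passed (list adjusted p from 0.0522 to 0.997), and the direction turned for Msn2/Msn4 (0.961), drug efflux (0.997), beta-oxidation (0.804) and ribosome biogenesis (0.555). By fry these lists had adjusted p = 0.994 for the deletant and 0.892 for the C404A mutant. Of 3517 unnamed probe sets outside the tested genes, 449 lay above background, and 1 was lower after LoaOOH in wild type, with 54 at an unadjusted p under 0.05. None passed in the responses of the mutants or in the response differences. Between genotypes 28 differed for the deletant and 13 for the C404A mutant against wild type control, 7 for the C404A mutant against the deletant, and 25 and 10 for the deletant and the C404A mutant against wild type after LoaOOH.

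For the 8 comparisons of 3 arrays with 3, the 10 splits of the arrays are too few for a share under 0.05. The real count and the highest of the other splits were 14 and 1 for LoaOOH in wild type, 194 and 0 in the deletant, 0 and 0 in the C404A mutant, 551 and 0 for the deletant and 449 and 0 for the C404A mutant against wild type control, 98 and 0 for the C404A mutant against the deletant, and 567 and 0 for the deletant and 402 and 0 for the C404A mutant against wild type after LoaOOH. For each response difference the real split gave 0 genes, so all 100 splits drawn had to give at least as many and say nothing on chance. The highest other counts were 1 for the deletant and 1261 for the C404A mutant, the latter in a split that exchanged genotypes among control arrays only and so carries the difference between genotypes.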

How the results depend on the processing

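The alternatives on chromosome V, the C404A replicate 2 pair and the fixed block per genotype and replicate number were chosen after the values were seen, and the others were set in advance.

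Of 458 gene results, 10912 repeats under the alternatives kept direction and side of the threshold, 385 passed it in addition, 1134 no longer passed and 12 reversed. Of 75 list results, 574 repeats kept their call, 212 lost it and 10 reversed, and 75 of the lost calls were those with the estimated correlation and 58 those with fry. These 75 are the lists that passed in the main fit, so calls that other lists gained are not counted. Quantile normalization, leaving out dim genes, the offset and the mean of probe sets kept every gene count within 1.5 times. Unless stated, the cause of a change was not tested. Signal over background limits genes such as SWI6 in the deletant, whose folds are lower bounds.

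The wild type response of 14 genes became 0 with the replicate block, the label prefix block, the CT arrays alone, a random replicate block and the unmoderated test, 696 with a random block within genotype, 317 with the compared groups only, 107 with trended and robust variances, 1231 with array weights, 9 at 1.5-fold, 1 with the fixed block within genotype, 479 without the C404A replicate 2 pair and 1046 without it with a random block within genotype. The deletant response of 194 became 0 with the replicate block, the label prefix block and the CT arrays alone, 127 with the random replicate block, 847 with the random block within genotype, 645 with array weights, 1 with the unmoderated test, 73 at 1.5-fold, 535 without the pair and 1270 without it with the random block. The C404A response of 0 became 217 without the pair and 834 without it with the random block. Deletant against wild type control (551) became 848 with array weights, 237 with the unmoderated test, 281 at 1.5-fold, 250 without chromosome V genes and 324 with the shift removed. The C404A mutant against wild type control (449) became 264 in the CT arrays, 136 with the unmoderated test, 198 at 1.5-fold, 94 without chromosome V genes and 180 with the shift removed. The C404A mutant against the deletant (98) became 15 in the CT arrays, 34 with the compared groups only, 3 with the unmoderated test and 45 at 1.5-fold. After LoaOOH the deletant against wild type (567) became 1092 with array weights, 341 with the unmoderated test, 273 at 1.5-fold, 255 without chromosome V genes and 325 with the shift removed, and the C404A mutant against wild type (402) became 187 with the compared groups only, 97 with the unmoderated test, 201 at 1.5-fold, 69 without chromosome V genes and 157 with the shift removed. Counts without chromosome V genes lack the calls of that chromosome and many calls elsewhere. The Benjamini-Hochberg cutoff depends on all genes of a fit, so removing the many chromosome V calls makes it stricter for the other genes. How much of the loss elsewhere this accounts for was not tested. Counts at 1.5-fold fall because genes under that fold are removed. Both response differences called 0 genes under every alternative.

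Leaving out an array or a replicate number gave 0 to 10 genes for the wild type response (0 without replicate 1 or 3), 0 to 59 for the deletant response (0 without replicate 1 or 3, 32 without replicate 2), 0 to 183 for the C404A response (48 without replicate 2), 277 to 484 for the deletant against wild type control (361 without wild type control replicate 1, 291 without replicate 1, 277 without replicate 2), 208 to 465 for the C404A mutant against wild type control (226 without replicate 1, 208 without replicate 2, 264 without replicate 3), 15 to 99 for the C404A mutant against the deletant (39, 30 and 15 without replicates 1, 2 and 3), 272 to 477 for the deletant after LoaOOH (294 without replicate 1, 272 without replicate 2) and 205 to 471 for the C404A mutant after LoaOOH (219 without replicate 1, 205 without replicate 2).

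With the chromosome V shift removed, genes on that chromosome turned in direction, as the construction lowers each of them by the shift. RNR1 turned to -0.56 and -0.21 in control and -0.49 and -0.17 after LoaOOH (deletant and C404A mutant against wild type), RPL34A to -0.56 in control and -0.61 after LoaOOH in the deletant, RPS26B to -0.50 in control and RPS8B to -0.61 after LoaOOH there, NUG1 to -0.19 and -0.28 in control and -0.18 in the deletant after LoaOOH, and GLC3 to -0.0212 in the C404A mutant after LoaOOH. Lists that turned were the proteasome in the C404A response without replicate 1 (list adjusted p = 0.754, range over replicate numbers 0.00833 to 0.754), and in the response difference of the C404A mutant Msn2/Msn4 (0.961), drug efflux (0.997), ribosome biogenesis (0.555) and beta-oxidation (0.804) without the pair and 0.249, 0.749, 0.0025 and 0.0793 without replicate 2. Over replicate numbers left out these ran from 8.94e-15 to 0.249, 1.32e-05 to 0.749, 8.23e-21 to 0.0025 and 2.15e-08 to 0.0793. Msn2/Msn4 in the C404A mutant against wild type after LoaOOH turned without replicate 2 (0.905, range 0.000145 to 0.905).

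As a block in all genotypes, the replicate number changed the calls of 3 lists, the proteasome in the C404A response (0.0648), MBF in the C404A mutant against wild type control (0.051) and the DNA damage list in the deletant after LoaOOH (0.0705). The fixed block within genotype ended the calls given in the 2 paired responses and no other list call. The replicate number had a consensus correlation of -0.0666 over all arrays and 0.391 within genotype. Lists were not run with random blocks, and the JC arrays, 1 per group, allow no test among themselves.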

Other observations

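The tests of these genes were chosen after their values were seen, and no p-value of a list is given for that reason.

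Genes under nitrogen catabolite repression were higher in the deletant. Of 14 measured, 9 rose in untreated deletant cells against wild type, among them the ammonium permease gene MEP2 (1.62 ± 0.149, adjusted p = 2.11e-06), the allantoin pathway gene DAL3 (1.18, adjusted p = 9.28e-05), the amino acid permease gene GAP1 (0.89, adjusted p = 0.000148) and the urea transporter gene DUR3 (0.89, adjusted p = 0.00496). In the C404A mutant against the deletant 9 of the 14 were lower, with MEP2 at -1.08 and DAL80 at -0.80, and against wild type MEP2 was higher by 0.54 (adjusted p = 0.0356) and MEP1 lower at -0.41 (adjusted p = 0.0383), where 0 of the 14 were called without both C404A replicate 2 arrays.

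Of 15 phosphate starvation genes, 5 were lower, 2 higher and 8 not called in untreated deletant cells against wild type, and 5 were lower, 1 higher and 9 not called in the C404A mutant. The higher ones lie on chromosome V, VTC1 at 0.50 in the deletant and 0.40 in the C404A mutant and PHM8 at 0.68 in the deletant. Among the others PHO84 was at -3.55 in the deletant and -2.97 in the C404A mutant, the acid phosphatase gene PHO5 at -1.27 (adjusted p = 0.0293) and -1.40, the polyphosphate synthesis gene VTC3 at -0.41 (adjusted p = 0.00759) and -0.45 (adjusted p = 0.00491), PHO11 at -1.21 (adjusted p = 0.0115) and -0.86 (adjusted p = 0.0781, not called) and SPL2 at -1.58 (adjusted p = 0.0362) and -1.13 (adjusted p = 0.141, not called). Both comparisons share the wild type arrays, and between the mutants PHO84 differed by 0.58 (adjusted p = 0.588).

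Of 12 genes that yeast lowers when unsaturated fatty acids are supplied, 10 had negative and 2 positive values with LoaOOH in each genotype, and only IZH3 passed over all genes, in wild type (-0.39, adjusted p = 0.0449) and the deletant (-0.32, adjusted p = 0.0381). The positive ones were FAA1 (0.19 in wild type, adjusted p = 0.189) and GPT2 (0.26, adjusted p = 0.174). The fatty acid desaturase gene OLE1 was at -1.18 in wild type (adjusted p = 0.109) and -1.11 in the deletant (adjusted p = 0.117), and the acyl-CoA synthetase gene FAA4 at -1.52 (adjusted p = 0.0589) and -1.39 (adjusted p = 0.0551). Without both C404A replicate 2 arrays, 7 of the 12 fell in wild type, 4 in the deletant and 7 in the C404A mutant, where FAA4 fell by 1.65 (adjusted p = 0.0336), INA1 by 3.10 (adjusted p = 0.0264) and ANB1 by 1.05 (adjusted p = 0.00333).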
